A study of Mus musculus with 35 samples.

How the data were processed

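RNA from the suprarenal aorta of male ApoE-deficient mice was measured on 35 two-colour Agilent whole-genome arrays, one aorta per array per the labels. The mice had received saline or angiotensin II at 1000 ng/kg/min from an osmotic minipump for 7, 14 or 28 days. Saline was held by 17 arrays, 6, 6 and 5 at 7, 14 and 28 days. Angiotensin II, written Ang II from here on, was held by 18 arrays, 4, 5 and 6 at these times and 3 from aortas that had dissected by 7 days. Groups were taken from the labels alone. Per the labels the aorta was labelled with Cy5 after linear amplification, and a universal mouse reference RNA was labelled with Cy3 by direct reverse transcription on every array. No array swapped the dyes, so a ratio to the reference was read only as a difference between aortas.

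The deposited scanner files hold the fluorescence intensity of each spot and its local background in both channels, and the authors made them with Agilent Feature Extraction 9.5.3.1, per the submitters' processing notes. The log10 ratio of aorta to reference in those files was computed by that software, per the file headers. The deposited series table holds log2 ratios of aorta to reference. Their slope on the scanner's log10 ratio ran from 3.321 to 3.341 and their correlation with it from 0.986 to 1 over the arrays. Direction and log base are therefore known, the array medians ran from -0.0675 to 0.109, and any further normalization by the authors is not stated. Each array carried 45018 spots, of which 43379 were gene spots and 1639 were controls, and the gene spots held 41174 different probes.

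The share of spots well above background in the aorta channel ran from 45 to 84.8 percent with a median of 57.1 percent, and in the reference channel from 54.5 to 71.9 percent. A gene near background has a compressed ratio, and the number of arrays limits the precision of a mean.

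Probes were named through their accession in a RefSeq gene table of the mouse assembly for 24375 probes, by a current symbol for 6303 and by an older symbol for 2418, and 8078 kept the name in the file. Only names were taken from that table. Spots of one probe were averaged, and one probe was kept per symbol, the one with the highest mean intensity over all arrays. A probe was tested if the aorta channel was well above background on at least 3 arrays, which left 27825 probes and 18672 genes. Values flagged by the scanner software were left out, which touched 134 genes.

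The main processing was fixed before the data were examined, together with the comparisons, the gene lists, the named genes and the first set of alternatives. Background was subtracted with the normexp method with an offset of 50 on mean signal and local median background, and log2 ratios were normalized within each array by loess, with control spots and spots the software had marked as non-uniform given no weight. Work was done in R 4.3.3 with limma 3.58.1, statmod 1.5.0 and the data.table package in version 1.17.8. One limma model with 7 group means was fitted to all 35 arrays, with 28 residual degrees of freedom and 2.72 prior degrees of freedom. The comparisons were Ang II against saline at 7, 14 and 28 days and as the mean of the 3 times, dissected Ang II against saline at 7 days, and dissected against non-dissected Ang II at 7 days. Further tests asked whether the effect of Ang II differed among times and whether the saline arrays changed over time. Genes were called at an adjusted p of 0.05 (Benjamini-Hochberg over the genes of a comparison). The p-values measure the spread between these aortas.

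Gene lists were tested with camera of the same package at a preset correlation between genes of 0.01, adjusted over the 38 lists of a comparison, and again with an estimated correlation and with fry. The lists were contractile smooth muscle, fibrillar and network collagens, collagen processing enzymes, elastic fibre components, matricellular proteins and proteoglycans, extracellular proteases and inhibitors, TGF-beta and BMP signalling, and bone and cartilage. Immune lists were monocytes and macrophages, neutrophils, T cells, B cells and plasma cells, mast cells, cytokines and chemokines, adhesion and leukocyte recruitment receptors, complement and interferon response. Lists of other cells were endothelium, fibroblasts and adventitia, white and common adipocyte, brown adipocyte, adrenal cortex, chromaffin and sympathetic neurons, Schwann cells and myelin, skeletal muscle, hepatocyte, kidney tubule, erythroid and platelets. The remaining lists were cell cycle, renin-angiotensin system, oxidative stress, glycolysis and hypoxia, oxidative phosphorylation, fatty acid oxidation, cholesterol synthesis and uptake, immediate early, and circadian clock. Most lists share no member with another list, and fibroblasts and adventitia shares the most, 4 members. Many members of the lists of other cells are also expressed in an aorta.

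Named genes were drawn from the 8 largest rises and 8 largest falls among called genes with a symbol whose arrays did not overlap between groups, from the 4 called members with the smallest p of each called list, and from 28 genes fixed in advance for their known place in aortic aneurysm, which are given in every comparison except for what is not reported here. For each test of change over time the 5 genes with the smallest p were named. Where a gene was near background on every array of one group its change is printed as at least so many fold, a bound taken on the intensity of the aorta channel alone, with the background limit in place of the dim group.

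The scripts were tested on simulated data in which 200 of 18672 genes were changed by known folds. For Ang II against saline at 7, 14 and 28 days, 95.5, 90.9 and 95.5 percent of genes changed 4-fold were recovered, and 61.2, 76.1 and 71.6 percent of those changed 2-fold. For dissected aortas against saline they were 97 and 58.2 percent, and against non-dissected 84.8 and 68.7 percent. False calls numbered 10, 1, 5, 8 and 5 in that order. A shifted list was called in each comparison and 0 others, but random splits of real arrays called medians of 9 to 17 lists.

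Alternatives fixed in advance were no background correction, the scanner software's processed signals with median centring, median centring in place of loess, Aquantile and scale normalization between arrays, the aorta channel alone after quantile normalization, and the authors' own values. Others were no filter on dim probes, a filter for both channels on 90 percent of arrays (17717 probes), the mean of a gene's probes, a fit on only the groups compared, eBayes with trend and robust settings, array quality weights, and slide, scan day or replicate number as a block. The remaining ones left out each array in turn, or asked for a fold change of at least 1.5, or took an unadjusted p of 0.01 for calls at all 3 times. Every array sat on one of 11 slides, each holding more than 1 group, and was scanned on one of 2 days.

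A further 5 alternatives were chosen after seeing the data. These left out 2 arrays in doubt, took each scan day alone, repaired the background fit or left out the arrays of poor fit. The last added 6 neighbouring tissue scores as covariates, namely brown adipocyte, neurons, hepatocyte, kidney tubule, skeletal muscle and the immune B cell list. On 5 arrays 3 to 6 spots in a bright smear of local background had drawn the fitted aorta background far below that of the other arrays. Ratios there were compressed, with a median absolute log2 ratio of 0.04 to 0.16 against 0.17 to 0.40 on the others and 0.25 to 0.29 after repair. The 5 arrays were saline at 7 days replicate 5, saline at 28 days replicates 1, 2 and 4, and Ang II at 28 days replicate 2.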

Results

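Suprarenal aortas of ApoE-deficient mice were compared between Ang II and saline at 7, 14 and 28 days, with 4, 5 and 6 Ang II aortas and 6, 6 and 5 saline aortas. A further 3 Ang II aortas had dissected by 7 days. Among 18672 genes tested with limma, 5066 changed at 7 days, 449 at 14 days and 168 at 28 days. Values are log2 changes, given with a standard error where one is printed.

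After 7 days of Ang II 5066 genes changed. Of the named genes Cthrc1, a secreted protein of activated fibroblasts, rose most, by 5.06 (standard error 0.418, adjusted p = 1.45e-09), from -0.18 with a standard deviation of 0.208 in 6 saline aortas to 4.88 with 0.201 in 4 Ang II aortas. Timp1, an inhibitor of metalloproteinases, rose by 4.86 (0.513), and Col8a1, a short-chain collagen of the vessel wall, by 4.85 (0.517). Falls without overlap between groups were led by Idh3a and Sucla2 of the citric acid cycle, by 2.93 (0.657) and 2.90 (0.605). In all 2710 genes rose and 2356 fell, 1906 of the 5066 at least 2-fold.

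The other largest rises among named genes were Col1a1, the main chain of type I collagen, at 4.56 (0.651, adjusted p = 9.43e-06), Esm1, a proteoglycan secreted by endothelium, at 4.40 (0.684), and Ccn5, a matricellular growth regulator, at 3.92 (0.608). Piezo2, a stretch-gated channel, rose by 3.90 (0.276, adjusted p = 5.08e-11) and Col3a1, the chain of type III collagen, by 3.81 (0.564). Of 19 fibrillar and network collagens 17 rose, 17 adjusted over the list alone, with a median of 2.74 (adjusted p = 3.78e-14, and adjusted p = 0.144 with an estimated correlation). Collagen processing enzymes, which fold and crosslink these chains, rose for 17 of 20, 17 adjusted over the list alone, with a median of 1.81 (adjusted p = 5.5e-14, and adjusted p = 0.144 with an estimated correlation). The crosslinking oxidases Lox and Loxl2 rose by 3.56 (0.434) and 2.80 (0.328).

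Elastic fibre components rose for 10 of 17, 11 adjusted over the list alone, with a median of 1.57 (adjusted p = 6.06e-08, and adjusted p = 0.248 with an estimated correlation). Fibulin 2, encoded by Fbln2, rose by 2.37 (0.227) and the microfibril gene Fbn1 by 3.08 (0.471). Eln itself was at 0.89 with an adjusted p of 0.15. Matricellular proteins and proteoglycans, which signal from the matrix to cells, rose for 17 of 22, 17 adjusted over the list alone, with a median of 1.98 (adjusted p = 4.35e-09, and adjusted p = 0.265 with an estimated correlation). The fixed genes of this kind that rose were Spp1 at 3.02, Thbs1 at 2.05, Tnc at 1.99, Postn at 1.85 and Ccn2 at 2.20.

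Extracellular proteases and inhibitors rose for 15 of 33, 16 adjusted over the list alone, with a median of 0.77 (adjusted p = 9.93e-08, and adjusted p = 0.18 with an estimated correlation). The membrane collagenase gene Mmp14 rose by 3.19 (0.346), the macrophage cathepsin gene Ctss by 2.78 (0.488) and the gelatinase gene Mmp2 by 1.51 (0.355). Mmp3 was at 1.44 with an adjusted p of 0.116, Mmp9 at 0.13 with 0.827, Mmp12 at 0.11 with 0.794 and Mmp13 at 0.54 with 0.438. Fibroblasts and adventitia rose for 8 of 14, 9 adjusted over the list alone, with a median of 1.04 (adjusted p = 0.000612, and adjusted p = 0.338 with an estimated correlation), including the fibroblast protease gene Fap at 1.89. TGF-beta and BMP signalling had 6 of 26 genes that rose and 1 that fell, the same counts adjusted over the list alone, with a median of 0.38 (adjusted p = 0.0248, and adjusted p = 0.608 with an estimated correlation). The growth factor genes Tgfb1 and Tgfb2 rose by 0.83 and 1.59. Bone and cartilage rose for 4 of 13, 4 adjusted over the list alone, with a median of 0.32 (adjusted p = 0.0263, and adjusted p = 0.338 with an estimated correlation), led by the cartilage collagen gene Col2a1 at 3.51 (0.478) and its regulator Sox9 at 1.55.

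Monocytes and macrophages rose for 23 of 28 genes, 24 adjusted over the list alone, with a median of 1.83 (adjusted p = 8.02e-16, and adjusted p = 0.129 with an estimated correlation). Trem2, a lipid-sensing receptor of macrophages, rose by 3.44 (0.426), Ms4a7 by 3.34 (0.361), the macrophage marker Adgre1 by 2.24 (0.272) and the lysosomal marker Cd68 by 1.69 (0.326). Cytokines and chemokines rose for 14 of 30, 14 adjusted over the list alone, with a median of 0.61 (adjusted p = 1.78e-06, and adjusted p = 0.2 with an estimated correlation). The alarmin gene Il33 rose by 2.80 (0.299), and the monocyte attractants Ccl8, Ccl9 and Ccl2 by 2.97, 2.61 and 1.42. Il1b rose by 1.45, and Il6 rose at least 2.5-fold. Adhesion and leukocyte recruitment receptors rose for 8 of 16, 8 adjusted over the list alone, with a median of 0.85 (adjusted p = 0.000913, and adjusted p = 0.338 with an estimated correlation), including the endothelial receptor Vcam1 at 1.80.

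Complement rose for 3 of 14, 3 adjusted over the list alone, with a median of 0.56 (adjusted p = 0.00557, and adjusted p = 0.338 with an estimated correlation), and its component gene C4b rose by 1.11. Interferon response rose for 6 of 21, 6 adjusted over the list alone, with a median of 0.33 (adjusted p = 0.0412, and adjusted p = 0.632 with an estimated correlation), with the antiviral gene Oas1a at 1.45. Cell cycle genes, expressed in dividing cells, rose for 28 of 30, 29 adjusted over the list alone, with a median of 1.57 (adjusted p = 1.18e-25, and adjusted p = 0.129 with an estimated correlation). The mitotic gene Kif20a rose by 2.84.

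Oxidative phosphorylation, the respiratory chain, fell for 27 of 31 genes, 29 adjusted over the list alone, with a median of -1.53 (adjusted p = 9.94e-13, and adjusted p = 0.328 with an estimated correlation). Fatty acid oxidation fell for 18 of 19, 18 adjusted over the list alone, with a median of -1.70 (adjusted p = 3.53e-08, and adjusted p = 0.329 with an estimated correlation). The complex genes Uqcrfs1, Ndufs1 and Atp5b fell by 2.46, 1.80 and 1.57, and the acyl-CoA dehydrogenase genes Acadm and Acadvl by 2.30 and 2.22. Beside them brown adipocyte genes, which mark a mitochondria-rich fat around the aorta, fell for 7 of 13, 7 adjusted over the list alone, with a median of -1.75 (adjusted p = 0.00246, and adjusted p = 0.485 with an estimated correlation). White and common adipocyte genes fell for 7 of 21, 7 adjusted over the list alone, with a median of -0.59 (adjusted p = 0.000913, and adjusted p = 0.485 with an estimated correlation). The lipase gene Lpl fell by 2.47 and the fat-synthesis genes Elovl6 and Fasn by 2.70 and 2.68.

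Glycolysis and hypoxia fell for 10 of 22 and rose for 1, with 15 lower and 1 higher adjusted over the list alone, and a median of -0.75 (adjusted p = 9.19e-05, and adjusted p = 0.2 with an estimated correlation). Bnip3 of mitochondrial turnover fell by 2.00 while the lactate carrier gene Slc16a3 rose by 1.59. Cholesterol synthesis and uptake fell for 7 of 21 and rose for 1, the same adjusted over the list alone, with a median of -0.88 (adjusted p = 0.00184, and adjusted p = 0.518 with an estimated correlation), including the squalene synthase gene Fdft1 at -1.94.

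Chromaffin and sympathetic neurons, a list of ganglion and adrenal medulla genes, fell for 9 of 15, 12 adjusted over the list alone, with a median of -2.01 (adjusted p = 0.000178, and adjusted p = 0.433 with an estimated correlation). The secretory granule gene Chgb fell by 3.88 (1.051), and its level was 5.94 with a standard deviation of 1.477 in saline. Schwann cells and myelin fell for 6 of 13 and rose for 1, with 8 and 1 adjusted over the list alone, and a median of -0.72 (adjusted p = 0.00403, and adjusted p = 0.345 with an estimated correlation). For hepatocyte, with secreted liver proteins, 0 of 11 genes were called by limma and 0 adjusted over the list alone at a median of -1.66 (adjusted p = 0.0412, and adjusted p = 0.639 with an estimated correlation). Agtr1a, the main Ang II receptor gene, fell by 2.57 (0.787).

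Contractile smooth muscle genes did not pass as a list (median 0.10, adjusted p = 0.917), with Acta2 at 0.38 and Myh11 at 0.26. Lists without a call at 7 days were neutrophils at 0.11, T cells at 0.00, B cells and plasma cells at 0.08, mast cells at 0.14, endothelium at 0.02, adrenal cortex at 0.01, skeletal muscle at 0.17, kidney tubule at -0.09, erythroid at 0.19 and platelets at -0.02. The renin-angiotensin system stood at 0.09, oxidative stress at 0.34, immediate early at 0.16 and circadian clock at -0.31. Single genes without a call were S100a8 at 0.15, Hba-a1 at 0.32 and Apoe at 0.01.

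The count at 7 days was 3201 and 3262 without Ang II replicates 2 and 1, and 98 of 110 named genes kept their calls whichever array was left out. With slide as a block it was 3232, 2030 higher and 1202 lower, with scan day as a block 4818, within scan day 1 2747 and within scan day 2, with 1 Ang II array, 205, 192 higher and 13 lower. It was 756, 622 higher and 134 lower, with neighbouring tissue scores as covariates. There oxidative phosphorylation was at -0.82, fatty acid oxidation at -0.69 and cholesterol synthesis, which lost its call, at -0.07. Brown adipocyte and hepatocyte lists were at 0.13 and 0.06 within scan day 2. Median centring gave 1563 genes, scale normalization 878, 695 higher and 183 lower, and array weights 7901.

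After 14 days of Ang II 449 genes changed, with Cthrc1, Col8a1 and Col1a1 again among the largest named rises. Ecrg4, a secreted precursor of growth-regulating peptides, rose by 3.43 (0.53, adjusted p = 0.000883), from 1.29 with a standard deviation of 0.498 in 6 saline aortas to 4.73 with 0.771 in 5 Ang II aortas. Cthrc1 rose by 3.42 (0.392), Col8a1 by 3.03 (0.485) and Col1a1 by 3.01 (0.61). The growth factor gene Fgf18 rose by 2.72 (0.366) and Piezo2 by 2.37 (0.259). In all 211 genes rose and 238 fell, 101 of the 449 at least 2-fold.

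Fibrillar and network collagens rose for 9 of 19, 14 adjusted over the list alone, with a median of 1.45 (adjusted p = 4.44e-12, and adjusted p = 0.403 with an estimated correlation), including Col1a2 at 2.48, Col11a1 at 2.37, Col3a1 at 2.37 and Col12a1 at 1.58. Collagen processing enzymes rose for 2 of 20, 6 adjusted over the list alone, with a median of 0.52 (adjusted p = 6.61e-05, and adjusted p = 0.546 with an estimated correlation), among them the procollagen protease gene Bmp1 at 1.47 and Loxl2 at 1.31. Elastic fibre components rose for 4 of 17, 6 adjusted over the list alone, with a median of 0.86 (adjusted p = 6.61e-05, and adjusted p = 0.546 with an estimated correlation). Matricellular proteins and proteoglycans rose for 2 of 22, 7 adjusted over the list alone, with a median of 0.65 (adjusted p = 6.99e-05, and adjusted p = 0.546 with an estimated correlation), namely Cilp at 1.59 and Comp at 1.77. Extracellular proteases and inhibitors rose for 5 of 33, 7 adjusted over the list alone, with a median of 0.36 (adjusted p = 0.00044, and adjusted p = 0.546 with an estimated correlation), with Timp1 at 2.47, Mmp14 at 1.70 and Mmp2 at 1.60.

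Fibroblasts and adventitia rose for 1 of 14, 2 adjusted over the list alone, with a median of 0.65 (adjusted p = 0.000218, and adjusted p = 0.546 with an estimated correlation), the gene being Fap at 1.37. Monocytes and macrophages rose for 2 of 28, 11 adjusted over the list alone, with a median of 0.74 (adjusted p = 1.52e-09, and adjusted p = 0.403 with an estimated correlation), Ms4a7 at 2.02 and Trem2 at 1.96. Cytokines and chemokines rose for 2 of 30, 5 adjusted over the list alone, with a median of 0.12 (adjusted p = 0.0341, and adjusted p = 0.634 with an estimated correlation), Ccl8 at 2.18 and Il33 at 1.17. Complement rose for 1 of 14, 3 adjusted over the list alone, with a median of 0.49 (adjusted p = 0.000218, and adjusted p = 0.411 with an estimated correlation), the gene being C4b at 1.03.

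In 5 other called lists 0 genes passed with limma. Interferon response, with 0 adjusted over the list alone, had a median of 0.30 (adjusted p = 0.00433, and adjusted p = 0.565 with an estimated correlation). Cell cycle, with 4 higher and 1 lower adjusted over the list alone, stood at 0.34 (adjusted p = 2e-05, and adjusted p = 0.546 with an estimated correlation). Contractile smooth muscle, with 0 adjusted over the list alone, stood at -0.46 (adjusted p = 0.0326, and adjusted p = 0.773 with an estimated correlation), with Acta2 at -0.74 and Myh11 at 0.38. Oxidative phosphorylation, with 0 adjusted over the list alone, stood at -0.34 (adjusted p = 0.0153, and adjusted p = 0.806 with an estimated correlation). Cholesterol synthesis and uptake, with 1 adjusted over the list alone, stood at 0.58 (adjusted p = 6.99e-05, and adjusted p = 0.546 with an estimated correlation).

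Lists of neighbouring tissue moved at 14 days as well. Kidney tubule fell for 4 of 9, 7 adjusted over the list alone, with a median of -0.99 (adjusted p = 1.85e-05, and adjusted p = 0.403 with an estimated correlation). The cadherin Cdh16 fell by 1.46, the endocytic receptor gene Lrp2 by 1.53, the transporter gene Slc22a6 by 0.99 and the phosphate carrier gene Slc34a1 fell at least 2.14-fold. The kidney score ran from -0.29 to 2.06 among the 6 saline aortas and from -0.47 to -0.24 among the 5 Ang II aortas. In chromaffin and sympathetic neurons, with 0 genes called by limma and 0 adjusted over the list alone, the median was 1.28 (adjusted p = 0.000218, and adjusted p = 0.546 with an estimated correlation). Adrenal cortex, with 0 genes called and 1 adjusted over the list alone, stood at 0.31 (adjusted p = 0.0302, and adjusted p = 0.546 with an estimated correlation). Platelets, with 0 of 11 called and 0 adjusted over the list alone, stood at -0.21 (adjusted p = 0.0356, and adjusted p = 0.661 with an estimated correlation).

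The elongation factor gene Ell2 fell by 1.17, the cyclin gene Ccni by 1.13 and the chloride channel gene Ano1 by 0.98. Not passing were Agtr1a at 1.10, Eln at 0.65, Lox at 0.99, Fbn1 at 0.94, Spp1 at 0.59, Postn at 0.70, Tnc at 0.41, Thbs1 at 0.81, Ccn2 at 0.17 and Tgfb1 at 0.30. The same held for Mmp3 at 0.85, Mmp9 at -0.32, Mmp12 at 0.05, Mmp13 at -0.25, Ccl2 at -0.29, Il6 at 0.58, Il1b at -0.11, Cd68 at 0.76, S100a8 at -1.47, Hba-a1 at 0.51 and Apoe at 0.10.

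Leaving out one array moved the 14-day count to 73, 92 and 247 without Ang II replicates 4, 3 and 2. It was 132, 194 and 721 without saline replicates 1, 2 and 6, and 15 of 40 named genes kept their calls throughout. Slide as a block gave 316 genes and scan day as a block 444, with 19 genes within scan day 1, 11 higher and 8 lower, and 1 within scan day 2. The fit on only these groups gave 80 higher and 33 lower, and the fit without the 2 arrays in doubt 52 and 29. With neighbouring tissue as covariates the count was 209, 150 higher and 59 lower, with contractile smooth muscle at 0.11 and cholesterol synthesis at -0.01. Median centring gave 121, with 35 higher and 86 lower and the median of all genes at -0.14, the aorta channel alone 293, array weights 993 and scale normalization 6. The authors' values gave 184 higher and 396 lower. Within scan day 1 contractile smooth muscle was at 0.18, with median centring the interferon response was at -0.02, and without saline replicate 3 platelets were at 0.02.

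After 28 days of Ang II the called lists were led by monocytes and macrophages. Of the named genes Col8a1 rose most, by 2.91 (0.485, adjusted p = 0.00173), from -1.60 with a standard deviation of 0.444 in 5 saline aortas to 1.31 with 1.21 in 6 Ang II aortas. Trem2 rose by 2.79 (0.399, adjusted p = 0.000446), Fgf18 by 2.71 (0.366), the lymphoid cytokine receptor gene Il7r by 2.61 (0.563) and Ctss by 2.49 (0.458). Ccl8 rose by 2.40, Timp1 by 2.37 and Ms4a7 by 2.35. In all 157 genes rose and 11 fell, 122 of the 168 at least 2-fold.

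Monocytes and macrophages rose for 14 of 28 genes, 23 adjusted over the list alone, with a median of 1.41 (adjusted p = 5.81e-27, and adjusted p = 0.0234 with an estimated correlation). The galectin gene Lgals3 rose by 2.28 (0.344), the pore-forming gene Mpeg1 by 2.23 (0.364) and Cd68 by 1.42. Extracellular proteases and inhibitors rose for 5 of 33, 10 adjusted over the list alone, with a median of 0.35 (adjusted p = 6.32e-05, and adjusted p = 0.346 with an estimated correlation). The macrophage elastase gene Mmp12 rose at least 2.02-fold and the cathepsin gene Ctsb by 0.94. Oxidative stress rose for 2 of 22, 7 adjusted over the list alone, with a median of 0.39 (adjusted p = 0.000775, and adjusted p = 0.121 with an estimated correlation), including the phagocyte oxidase gene Cybb at 1.66. Cytokines and chemokines rose for 4 of 30, 9 adjusted over the list alone, with a median of 0.25 (adjusted p = 0.00127, and adjusted p = 0.523 with an estimated correlation).

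Adhesion and leukocyte recruitment receptors rose for 1 of 16, 6 adjusted over the list alone, with a median of 0.72 (adjusted p = 3.29e-05, and adjusted p = 0.33 with an estimated correlation). Complement rose for 1 of 14, 4 adjusted over the list alone, with a median of 0.55 (adjusted p = 0.000226, and adjusted p = 0.283 with an estimated correlation), through C4b at 1.29. The renin-angiotensin system rose for 1 of 17, 1 adjusted over the list alone, with a median of 0.50 (adjusted p = 0.00351, and adjusted p = 0.283 with an estimated correlation), through Prcp, a peptidase that trims angiotensins, at 1.03. Collagens rose for 1 of 19, 6 adjusted over the list alone, with a median of 0.90 (adjusted p = 8.02e-06, and adjusted p = 0.498 with an estimated correlation). Elastic fibre components rose for 1 of 17, 2 adjusted over the list alone, with a median of 0.42 (adjusted p = 0.0107, and adjusted p = 0.673 with an estimated correlation), through the latent growth factor binder Ltbp2 at 1.68. Matricellular proteins rose for 1 of 22, 6 adjusted over the list alone, with a median of 0.56 (adjusted p = 0.0019, and adjusted p = 0.673 with an estimated correlation), through Thbs1 at 1.59.

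For 10 further called lists 0 genes passed with limma. Medians were 0.34 for collagen processing enzymes with 2 adjusted over the list alone (adjusted p = 0.00317), 0.39 for T cells with 1 (adjusted p = 0.00876), 0.80 for B cells and plasma cells with 1 (adjusted p = 0.00169) and 0.36 for interferon response with 3 (adjusted p = 0.00358), each with adjusted p = 0.673 with an estimated correlation. With 0 adjusted over the list alone stood contractile smooth muscle at -0.33 (adjusted p = 0.00407), endothelium at 0.62 (adjusted p = 0.000257), white and common adipocyte at 0.50 and neurons at -0.69 (adjusted p = 0.00915 for both), each again with adjusted p = 0.673 with an estimated correlation. Skeletal muscle was at 0.94 (adjusted p = 0.0144, and adjusted p = 0.69 with an estimated correlation) and circadian clock at -0.29 (adjusted p = 0.00257, and adjusted p = 0.283 with an estimated correlation), also with 0 adjusted over the list alone. The skeletal muscle score ran from -0.82 to 2.76 over the 6 Ang II aortas and the B cell score from -0.50 to 2.79.

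The genes named for falls at 28 days were Rhpn2 at -1.02, Mettl15 at -0.60, the energy-sensing kinase gene Prkaa1 at -0.60, Purb at -0.51, Ciao1 at -0.44 and Tbp at -0.37. Fixed matrix genes without a call were Col1a1 at 1.64, Col3a1 at 1.08, Eln at 0.53, Lox at 0.93, Fbn1 at 0.71, Spp1 at 2.44, Postn at 0.08, Tnc at 0.63, Ccn2 at 0.48 and Tgfb1 at 0.40. Others without one were Agtr1a at 0.30, Acta2 at -1.13, Myh11 at -0.26, Mmp2 at 0.82, Mmp3 at 0.21, Mmp9 at -0.06, Mmp13 at -0.03, Ccl2 at 0.17, Il6 at -0.10, Il1b at 0.06, S100a8 at -0.22, Hba-a1 at 0.37 and Apoe at 0.39.

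Without the 5 arrays of poor fit 1 gene was called, 0 of 29 named genes kept their calls and all 29 kept their direction, while the repaired fit gave 212 genes, 178 higher and 34 lower. Single arrays left out gave 68, 82, 87 and 307 without saline replicates 4, 1, 2 and 3, and 70 and 416 without Ang II replicates 5 and 2. Slide as a block gave 653, 553 higher and 100 lower, and scan day as a block 161, with 11 within scan day 1 and 1469, 930 higher and 539 lower, within scan day 2. The fit on only these groups called 0 genes with limma, neighbouring tissue covariates left 96, median centring gave 67 and array weights 260. The scanner's processed signals gave 292 higher and 64 lower, the aorta channel alone 225 and 61, no background correction 167 and 34, scale normalization 2721 and 1376, and the authors' values 427 genes.

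Signs of 28-day lists also turned under some settings. Within scan day 1 T cells were at -0.30, B cells were called at -0.43 and contractile smooth muscle at 0.76 (adjusted p = 0.000394). The last was at -1.45 within scan day 2 (adjusted p = 6.98e-09) and 0.04 without saline replicate 5. Within scan day 2 collagens were at -0.15, collagen processing at -0.16, elastic fibres at -0.14, matricellular proteins at -0.45 (adjusted p = 0.0343) and complement at -0.00. Endothelium was at -0.18 and -0.15 with the scanner's and the authors' values, and white adipocyte at -0.15 with array weights. With the repaired fit 17 of 20 lists kept their calls, and endothelium at 0.15, white adipocyte at 0.12 and the renin-angiotensin system at 0.21 did not. Without the arrays of poor fit 14 did, and those lost were collagen processing at 0.23, elastic fibres at 0.01, matricellular proteins at 0.06, endothelium at 0.25, skeletal muscle at 1.01 and the renin-angiotensin system at 0.29. Monocytes and macrophages were at 1.28 and 1.65 within scan days 1 and 2, and 1.57 with slide as a block.

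At all 3 times 39 genes were called in one direction, 36 higher and 3 lower. Trem2, Ms4a7, Timp1, Col8a1, Cthrc1 and Ccl8 were among them. Fgf18 stood at 3.50, 2.72 and 2.71, Ecrg4 at 3.18, 3.43 and 2.31, Piezo2 at 3.90, 2.37 and 1.83 and the growth factor gene Igf1 at 2.13, 1.26 and 1.33 at 7, 14 and 28 days. The 3 lower genes were Purb, Mettl15 and Bhlhb9, the last at -0.89, -0.79 and -0.87. Igf1 and Bhlhb9 were picked after their values were seen. Genes that rose at 7 and 14 days numbered 168 against 30.6 expected if independent, at 7 and 28 days 130 against 22.8, and at 14 and 28 days 38 against 1.77. Genes that fell at both numbered 114 against 30, 7 against 1.39 and 3 against 0.14. As the mean of the 3 times 2922 genes rose and 2170 fell, against 964 and 1249 with median centring and 991 and 410 at a fold of at least 1.5. The 39 ran from 21 to 68 with one array left out, and were 14, all higher, with median centring, 5 with scale normalization and 0 by limma without the arrays of poor fit.

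The effect of Ang II differed among times for 278 genes by an F test, and the 5 with the smallest p had all risen at 7 days. M1ap, a gene known from meiosis, rose by 2.00 at 7 days and 0.53 at 14 days and stood at 0.39 at 28 days, so that the effect at 14 days was lower by 1.47 (0.188, adjusted p = 0.000164). Gjb5, a gap junction gene, was lower by 1.84 at 14 days and by 2.15 (0.263, adjusted p = 2.83e-05) at 28 days than at 7 days. Flrt2, an axon guidance ligand gene, was lower by 1.92 and Peg12 by 1.32 at 28 days, and the procollagen protease gene Adamts3 by 1.34 at 14 days. Between 14 and 7 days 193 genes differed, 46 with a higher and 147 with a lower effect, and between 28 and 7 days 497, 128 higher and 369 lower. Between 28 and 14 days 0 genes differed with limma, and 1356 had an unadjusted p under 0.05, many expected by chance.

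These counts moved widely with single arrays. The count of 278 ran from 87 without Ang II 7-day replicate 2 to 561 without saline 28-day replicate 3, with 6 arrays that moved it more than 1.5-fold. The 193 ran from 28 without Ang II 7-day replicate 2 to 1018 without saline 14-day replicate 5, over 15 such arrays, and the 497 from 159 without Ang II 7-day replicate 2 to 1097 without saline 28-day replicate 3, over 14. With the repaired background fit the counts of 278 and 497 were 122 and 157, and with slide as a block 79 and 174. Median centring left 0 higher and 30 lower by limma for 14 against 7 days and 0 and 12 for 28 against 7 days. Array weights gave 1398 higher and 1201 lower for the first and 917 and 1027 for the second, for which the authors' values gave 20 and 210.

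In saline aortas alone 114 genes changed over time by an F test, and 494 differed between 28 and 14 days when that pair was tested alone. The replication licensing gene Dtl was higher by 1.39 at 28 than at 14 days, Aurkb, a mitotic kinase gene, by 1.51 and the interferon-inducible gene Ifi202b by 1.54, each with an F-test adjusted p of 0.0401. The cell cycle list stood at 0.43 between these times, with 7 of 30 genes higher and 14 adjusted over the list alone. The count was 0 by limma with the repaired background fit, and 0 without the arrays of poor fit. As first fitted it was 114, with 2372 at an unadjusted p under 0.05. Leaving out one array gave from 0, without each of 9 saline arrays in turn, to 610 without 28-day replicate 3.

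**Figure D1:**
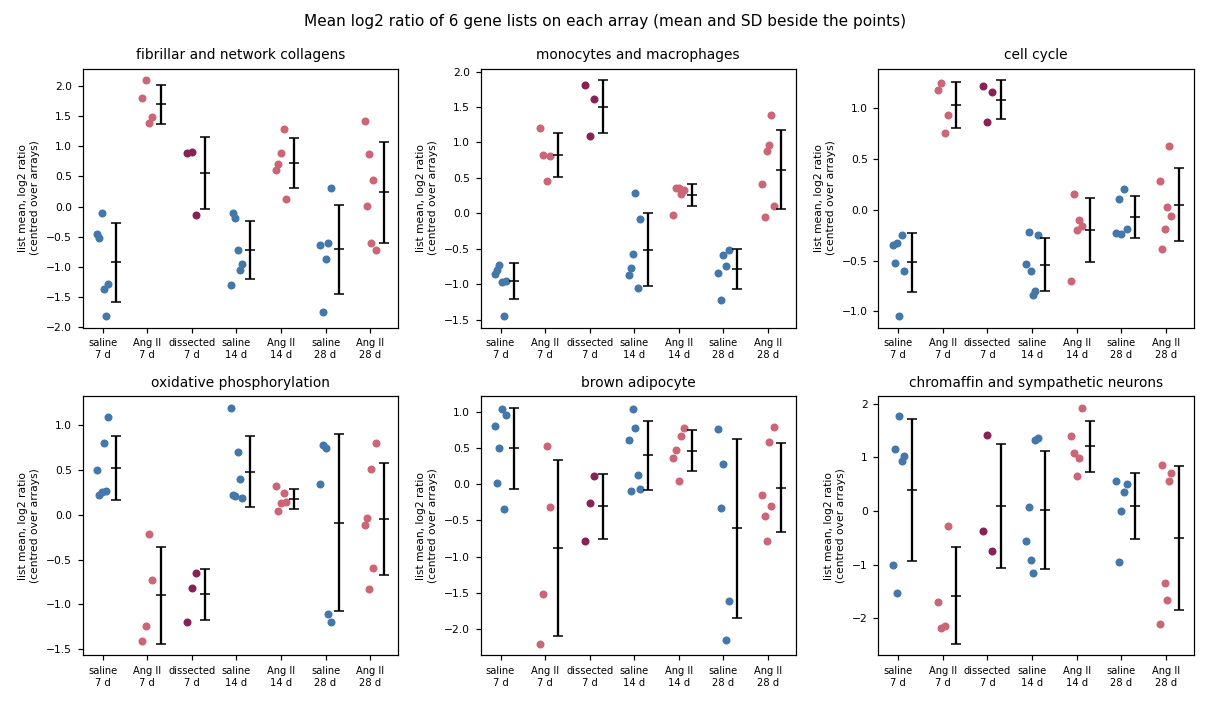
Scores of 6 gene lists in each of 35 arrays, with group means and standard deviations. The collagen score was highest in Ang II at 7 days, with a mean of 1.70, against -0.93 in saline at 7 days.

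Aortas that had dissected by 7 days differed from saline in 6814 genes. Of the named genes Timp1 rose most, by 5.07 (0.562, adjusted p = 6.3e-08), from -1.89 with a standard deviation of 0.779 in 6 saline aortas to 3.18 with 0.198 in 3 dissected ones. Trem2 rose by 4.99 (0.466), the fibroblast membrane gene Lrrc15 by 4.60 (0.492), the myeloid receptor gene Cd300lf by 4.50 (0.61) and the inflammasome gene Mefv by 4.38 (0.586). Pf4, a platelet chemokine gene also active in macrophages, rose by 4.30, the haem-degrading enzyme gene Hmox1 by 4.29 and Cthrc1 18.4-fold. In all 3526 genes rose and 3288 fell, 2780 of the 6814 at least 2-fold.

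Monocytes and macrophages rose for 27 of 28 genes, 27 adjusted over the list alone, with a median of 2.39 (adjusted p = 1.02e-15, and adjusted p = 0.264 with an estimated correlation), including Ms4a7 at 4.07, the Fc receptor genes Fcgr1 and Fcer1g at 3.77 and 3.30 and Cd68 at 2.41. Neutrophils rose for 7 of 15, 9 adjusted over the list alone, with a median of 1.16 (adjusted p = 0.00437, and adjusted p = 0.845 with an estimated correlation), including the growth factor receptor gene Csf3r at 2.85, the peptide receptor gene Fpr1 at 1.70 and S100a8 at 2.48. Cytokines and chemokines rose for 19 of 30 and fell for 1, with 20 and 1 adjusted over the list alone, and a median of 1.13 (adjusted p = 1.02e-05, and adjusted p = 0.541 with an estimated correlation), with Ccl8 at 3.01, Il1b at 3.02 and Il6 at least 2.25-fold higher. Adhesion receptors rose for 6 of 16, 6 adjusted over the list alone, with a median of 0.79 (adjusted p = 0.0291, and adjusted p = 0.845 with an estimated correlation). Platelets rose for 4 of 11, 4 adjusted over the list alone, with a median of 0.55 (adjusted p = 0.0463, and adjusted p = 0.921 with an estimated correlation).

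Collagens rose for 10 of 19, with 12 higher and 1 lower adjusted over the list alone, and a median of 1.28 (adjusted p = 0.000837, and adjusted p = 0.845 with an estimated correlation), with Col8a1 at 3.51, Col1a1 at 3.43 and Col3a1 at 1.98. Collagen processing enzymes rose for 11 of 20, 13 adjusted over the list alone, with a median of 1.01 (adjusted p = 6.67e-05, and adjusted p = 0.845 with an estimated correlation). Elastic fibre components rose for 6 of 17, 6 adjusted over the list alone, with a median of 0.99 (adjusted p = 0.0297, and adjusted p = 0.921 with an estimated correlation). Proteases and inhibitors rose for 14 of 33 and fell for 2, the same adjusted over the list alone, with a median of 0.71 (adjusted p = 0.000599, and adjusted p = 0.845 with an estimated correlation), with Mmp14 at 3.63, Adam8 at 3.73 and Mmp9 at 2.18 (0.378). Cell cycle rose for 26 of 30, 28 adjusted over the list alone, with a median of 1.62 (adjusted p = 2.46e-17, and adjusted p = 0.387 with an estimated correlation). Spp1 and Tgfb1 rose by 3.97 and 1.59.

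Oxidative phosphorylation fell for 21 of 31, 22 adjusted over the list alone, with a median of -1.59 (adjusted p = 2.35e-07, and adjusted p = 0.845 with an estimated correlation), and fatty acid oxidation for 12 of 19, 16 adjusted over the list alone, with a median of -1.86 (adjusted p = 3.99e-05, and adjusted p = 0.845 with an estimated correlation). Falls without overlap between groups included the mitochondrial ND4L at -3.85, the caveolar gene Cav2 at -3.50 and Lpl at -3.39. The hepatocyte list stood at -1.74 (adjusted p = 0.0855).

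Contractile smooth muscle stood at -0.86 with 5 of 24 genes lower, 4 adjusted over the list alone (adjusted p = 0.0924). The other lists without a call were matricellular proteins at 0.13, fibroblasts at 0.17, TGF-beta and BMP signalling at -0.27, bone and cartilage at 0.08, complement at 0.17, interferon response at 0.09, T cells at -0.06, B cells at 0.05, mast cells at -0.20, endothelium at 0.76, white and brown adipocyte at -0.08 and -0.79, adrenal cortex at -0.04, neurons at -0.07, Schwann cells at -0.47, skeletal muscle at -0.44, kidney tubule at 0.11, erythroid at 0.07, the renin-angiotensin system at -0.13, oxidative stress at -0.07, glycolysis at -0.69, cholesterol synthesis at -0.66, immediate early at 0.15 and circadian clock at -0.46. The matricellular score averaged -0.24 in dissected and 1.19 in non-dissected aortas. Not passing were Agtr1a at -1.66, Acta2 at -1.03, Myh11 at -0.02, Mmp2 at 0.64, Mmp3 at 0.28, Mmp12 at -0.09, Mmp13 at 0.38, Eln at 1.14, Lox at 0.94, Fbn1 at 0.29, Postn at 0.19, Tnc at 1.03, Thbs1 at 0.75, Ccn2 at -0.59, Ccl2 at 1.12, Hba-a1 at 0.78 and Apoe at 0.27.

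Both 7-day comparisons used the same saline aortas. Genes called in one direction in both numbered 3516, 1932 higher and 1584 lower, and fold changes correlated at 0.774 against 0.368 in simulations with no effect. With the saline aortas split 3 and 3 the mean correlation was 0.685, from 0.474 to 0.788. How far the shared saline raises the overlap was not tested. No left-out array moved the count of 6814 more than 1.5-fold, and 64 of 71 named genes kept their calls. Slide as a block gave 4338 genes, with oxidative phosphorylation at -0.99 and fatty acid oxidation at -0.95, scan day as a block 6586 and scan day 2 alone, on which all dissected aortas were scanned, 5739. Median centring put the median of all genes at -0.36 with 873 higher and 5438 lower, scale normalization called 2078, 1304 higher and 774 lower, and Myh11 was at 0.92 with the scanner's processed signals and 0.94 with the authors' values.

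Dissected aortas differed from non-dissected Ang II aortas of the same day in 1498 genes and, by camera, in 11 lists, of which 0 passed with an estimated correlation and 0 with fry. Arg1, an arginine-degrading enzyme gene of repair macrophages, rose by 3.33 (1.046, adjusted p = 0.045), from 1.04 with a standard deviation of 0.832 in 4 non-dissected aortas to 4.37 with 0.906 in 3 dissected ones. Timp3, a matrix-bound protease inhibitor gene, fell by 2.95 (0.492, adjusted p = 0.000488), Fbn1 by 2.78 (0.557) and the decoy receptor gene Tnfrsf11b by 2.99 (0.663). Pf4 rose by 2.48 (0.54) and the gelatinase gene Mmp9 by 2.05 (0.408). In all 572 genes rose and 926 fell, 450 of the 1498 at least 2-fold.

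Matricellular proteins and proteoglycans fell for 7 of 22, 14 adjusted over the list alone, with a median of -1.59 (adjusted p = 3.41e-06, and adjusted p = 0.961 with an estimated correlation). The small proteoglycan genes Aspn, Bgn and Prelp fell by 2.50, 2.41 and 2.02, Cilp by 1.90, Ccn3 by 3.31 and Ccn2 by 2.79. Collagens fell for 4 of 19 and rose for 1, with 6 and 1 adjusted over the list alone, and a median of -1.28 (adjusted p = 0.00011, and adjusted p = 0.961 with an estimated correlation), with the basement membrane gene Col4a1 at -1.61 and Col12a1 at -2.04. Collagen processing enzymes fell for 2 of 20, 5 adjusted over the list alone, with a median of -0.41 (adjusted p = 0.00537, and adjusted p = 0.985 with an estimated correlation), with Lox at -2.62 (0.513). Elastic fibre components fell for 1 of 17, 1 adjusted over the list alone, with a median of -0.56 (adjusted p = 0.00908, and adjusted p = 0.985 with an estimated correlation). Fibroblasts and adventitia fell for 2 of 14, 6 adjusted over the list alone, with a median of -0.81 (adjusted p = 0.00259, and adjusted p = 0.961 with an estimated correlation).

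TGF-beta and BMP signalling fell for 4 of 26 and rose for 1, with 9 and 1 adjusted over the list alone, and a median of -0.74 (adjusted p = 0.00392, and adjusted p = 0.961 with an estimated correlation). Its shared transducer gene Smad4 fell by 0.81, the endothelial receptor gene Acvrl1 by 1.24 and Bmp4 by 1.40 while Tgfb1 rose by 0.75. For contractile smooth muscle 0 of 24 genes were called by limma and 0 adjusted over the list alone, with a median of -0.84 (adjusted p = 0.00337, and adjusted p = 0.985 with an estimated correlation), Acta2 at -1.41 and Myh11 at -0.27.

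Neutrophils rose for 4 of 15, 5 adjusted over the list alone, with a median of 0.80 (adjusted p = 0.00188, and adjusted p = 0.961 with an estimated correlation). Platelets rose for 3 of 11, 3 adjusted over the list alone, with a median of 0.40 (adjusted p = 0.00325, and adjusted p = 0.961 with an estimated correlation). Monocytes and macrophages rose for 1 of 28, 0 adjusted over the list alone by limma, with a median of 0.61 (adjusted p = 0.00136, and adjusted p = 0.961 with an estimated correlation). Chromaffin and sympathetic neurons rose for 1 of 15, 4 adjusted over the list alone, with a median of 1.75 (adjusted p = 6e-04, and adjusted p = 0.961 with an estimated correlation), the gene being Chga at 3.08, and the neuronal genes Stmn3 and Pcsk1n rose by 3.12 and 2.50. The neuron score ran from -0.74 to 1.41 in dissected and from -2.19 to -0.27 in non-dissected aortas.

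Not passing between dissected and non-dissected aortas were Agtr1a at 0.91, Mmp2 at -0.87, Mmp3 at -1.16, Mmp12 at -0.19, Mmp13 at -0.16, Timp1 at 0.22, Col1a1 at -1.13, Col3a1 at -1.82, Eln at 0.25, Spp1 at 0.95, Postn at -1.67, Tnc at -0.95 and Thbs1 at -1.30. Others were Ccl2 at -0.30, Il6 at -0.18, Il1b at 1.58, Cd68 at 0.71, S100a8 at 2.34, Hba-a1 at 0.45 and Apoe at 0.26.

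All 3 dissected and 1 of 4 non-dissected aortas were scanned on day 2. Scan day as a block gave 873 genes, 315 higher and 558 lower, slide as a block 295, 84 higher and 211 lower, and scan day 2 alone 8, 2 higher and 6 lower, with matricellular proteins at -1.45, -1.45 and -1.51. Collagen processing lost its call with scan day as a block (-0.32, adjusted p = 0.0581) and within scan day 2 (-0.06, adjusted p = 0.354), where elastic fibres (-0.44), neutrophils (0.58) and platelets (0.29) lost theirs too. With neighbouring tissue covariates 702 genes were higher and 739 lower and 4 of 11 lists kept their calls. Those lost were collagens at -0.55 (adjusted p = 0.057), collagen processing at -0.07, elastic fibres at -0.34, fibroblasts at -0.56, TGF-beta and BMP signalling at -0.47, contractile smooth muscle at -0.53 and, by construction, neurons at 0.08. The count was 704 and 785 without dissected replicates 2 and 1, and 838 and 920 without non-dissected 2 and 1. Of 39 named genes 13 kept their calls throughout, 17 with scan day as a block and 6 with slide as a block. The fit on only these groups gave 2320 and array weights 5211. With median centring the median of all genes was -0.29 with 56 higher and 1798 lower, and scale normalization gave 45 higher and 32 lower. The scanner's and the authors' values gave 2721 and 2814. Eln was at -2.66 in the aorta channel alone.

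**Figure D2:**
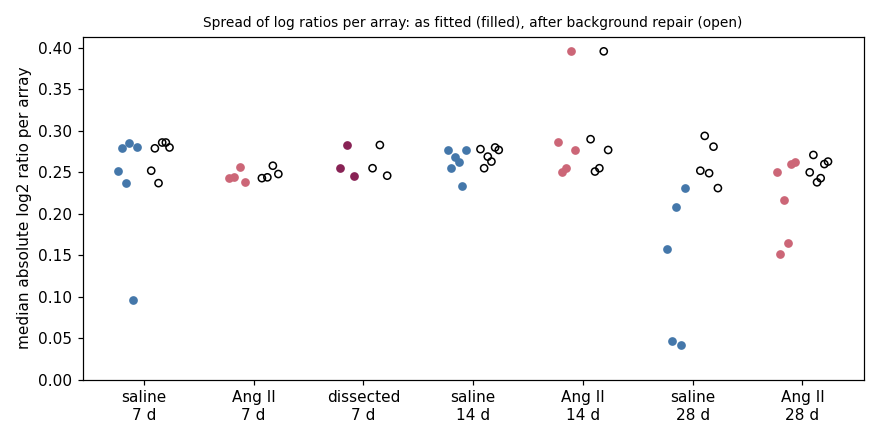
Median absolute log2 ratio of each array as fitted and after repair of the background fit. It was 0.04 to 0.16 on the 5 arrays of poor fit and 0.25 to 0.29 on the same arrays after repair.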

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

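The 2 tests of the neuron genes and the test of loess were chosen only after the result was seen, and the other tests below were planned.

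By camera on the difference itself the Ang II effect differed for 23 lists between 14 and 7 days, 21 between 28 and 7 and 12 between 28 and 14. With an estimated correlation 0 of them passed, with lowest adjusted p of 0.3, 0.0775 and 0.698, and fry called 8, 10 and 0. Between 14 and 7 days the median difference was -1.17 for collagens, -1.09 for collagen processing enzymes, -0.78 for elastic fibre components, -1.05 for matricellular proteins, -0.57 for proteases and -0.56 for TGF-beta and BMP signalling. It was -1.15 for monocytes and macrophages, -0.59 for neutrophils, -0.54 for cytokines, -0.90 for adhesion receptors, -1.27 for cell cycle and -0.41 for immediate early genes. Positive differences were 1.24 for oxidative phosphorylation, 1.51 for fatty acid oxidation, 0.73 for glycolysis and hypoxia and 1.33 for cholesterol synthesis. Neighbouring tissue lists gave 3.34 for chromaffin and sympathetic neurons, 0.83 for Schwann cells, 0.77 for white and 1.65 for brown adipocyte, 0.25 for adrenal cortex, 1.52 for hepatocyte and -0.97 for kidney tubule.

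Between 28 and 7 days the differences were -1.49 for collagens, -1.21 for collagen processing, -1.05 for elastic fibres, -1.19 for matricellular proteins, -0.54 for proteases, -0.65 for fibroblasts, -0.32 for TGF-beta and BMP signalling and -0.84 for bone and cartilage. They were -0.51 for monocytes and macrophages, -0.56 for cytokines, -1.49 for cell cycle and 0.70 for endothelium. Metabolic lists gave 1.51 for oxidative phosphorylation, 2.00 for fatty acid oxidation, 0.76 for glycolysis and 0.49 for cholesterol synthesis. White adipocyte was at 1.42, brown adipocyte at 2.52, neurons at 1.53, Schwann cells at 0.79 and hepatocyte at 2.04. Differences with 28 days carry the poor background fit of saline replicates 1, 2 and 4. After repair 17 of 20 lists kept their 28-day calls, but not endothelium (0.15) or white adipocyte (0.12).

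Between 28 and 14 days they were -0.50 for collagens, 0.67 for monocytes and macrophages, 0.67 for T cells, 0.94 for B cells, 0.77 for endothelium, 0.49 for adhesion receptors and 0.49 for oxidative stress. Cell cycle was at -0.18, cholesterol synthesis at -0.65, bone and cartilage at -0.29, neurons at -1.79 and kidney tubule at 0.84. By gene, 278 differed among times, 193 between 14 and 7 days and 497 between 28 and 7 days.

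Single arrays stood apart from their group in 18 of 240 tests of a list score or of a measure of array signal, where chance gives about 1 in 20 groups, or 12. In saline at 7 days replicate 5 stood apart for monocytes and macrophages at -1.45 (others -0.98 to -0.73) and for oxidative stress at -0.38 (-0.18 to -0.07), and replicate 4 for skeletal muscle at 1.36 (-0.88 to -0.25). In saline at 14 days replicate 6 stood apart for T cells at 1.69 (-0.50 to -0.16) and B cells at 1.52 (-0.72 to -0.15), and replicate 3 for platelets at 1.94 (-0.52 to 0.18). In saline at 28 days it was replicate 3 for B cells at 1.00 (-0.49 to -0.24), replicate 1 for adrenal cortex at 0.89 (-0.49 to -0.11) and replicate 4 for cholesterol synthesis at 0.67 (-0.35 to -0.06).

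In Ang II at 7 days replicate 2 stood apart for contractile smooth muscle at -0.064 (others 0.41 to 0.46) and for skeletal muscle at 1.41 (-0.88 to -0.63), replicate 3 for B cells at 0.74 (-0.45 to -0.25) and replicate 4 for circadian clock at -0.45 (-0.04 to -0.03). At 14 days it was replicate 1 for monocytes and macrophages at -0.02 (0.28 to 0.35) and for the renin-angiotensin system at 0.75 (0.18 to 0.33), and replicate 2 for adrenal cortex at 1.40 (-0.03 to 0.11) and platelets at -0.26 (-0.48 to -0.42). At 28 days it was replicate 2 for kidney tubule at 0.74 (-0.42 to -0.22).

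For neuron genes the mean over the list was -1.97 (standard error 0.685) at 7 days of Ang II (adjusted p = 0.433 with an estimated correlation) and 1.19 (0.642) at 14 days (adjusted p = 0.546 with an estimated correlation), where 0 of 15 genes were called by limma. The difference was 3.16 (0.939), and whether the 2 times differ in direction stays open. Over 17 saline aortas, with group means removed, the 9 catecholamine and 6 general neuronal members moved together with a correlation of 0.983 (permutation p 1e-05, the smallest that the permutations can give), and 0.973 without the 2 farthest arrays. A candidate explanation is that single aortas carried uneven amounts of ganglion or adrenal medulla, and a change in nerves of the wall stays untested.

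Oxidative phosphorylation genes were lower at 7 days. The list mean was -1.42 (standard error 0.353) and -0.61 (0.237) with the brown adipocyte score as a covariate, whose own difference was -1.38 (0.487) and whose slope was 0.591 (0.081). Less brown fat on Ang II aortas and lower respiration in the wall cannot be told apart, as many brown fat genes also follow mitochondrial content. Ucp1, a brown fat gene picked after its values were seen, stood at -0.90 (0.483, adjusted p = 0.164), from 6.62 in saline to 5.71. Loess was argued against, since the median shift was -1.73 with median centring and -1.53 with loess. Their camera adjusted p, 1.71e-11 at the preset and 0.328 with an estimated correlation, do not compare.

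Genes that differ between dissected and non-dissected aortas were set against scan day, since all 3 dissected aortas were scanned on day 2. Turned to the direction of each of 1498 called genes, the scan day difference in saline aortas had a median of 0.022, from 0.005 to 0.042 without one array, where the difference itself was 0.81. Scan day as a shared shift was therefore argued against. Whether the difference came with dissection itself or with its cause was not tested.

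Splits of the same arrays into groups of the same sizes were drawn for each count, with the real grouping counted as 1 of them. They asked whether chance could be excluded. It could for 7 days with 1 of 100 splits as large (real 5066, highest other 1720), for 14 days with 1 of 100 (449, 171), for the mean of 3 times with 1 of 100 (5092, 1022) and for genes at all 3 times with 1 of 100 (39, 0). It could also for dissected against saline with 1 of 84 (6814, 1920) and against non-dissected with 1 of 35 (1498, 490). At 28 days it could not, with 5 of 100 splits as large as 168 and the highest at 1371, which points to a structure of the samples.

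For the differing effects arrays changed places among times within saline and within Ang II, so a change over time in either also counts against chance. On that footing chance could be excluded among times with 1 of 100 (278, highest other 11) and between 28 and 7 days with 1 of 100 (497, 461). It could also between 14 and 7 days with 2 of 100 (193, 1122) and over time in saline with 2 of 100 (114, 1632). For 14 against 7 days and for saline the highest other split, several times the real count, points to a structure of the samples too, and the saline count was 0 by limma with the repaired background fit. Between 28 and 14 days, with 0 genes by limma and 1356 at an unadjusted p under 0.05, all 100 of 100 were as large (highest other 25). For the numbers of lists called it could not be excluded. As many lists as the real 23 at 7 days came in 11 of 100 splits (highest other 27), 18 at 14 days in 25 of 100 (24), 20 at 28 days in 21 of 100 (23), 12 for dissected against saline in 47 of 84 (23) and 11 against non-dissected in 16 of 35 (16).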

How the results depend on the processing

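Scan day alone, neighbouring tissue covariates, the repaired background fit and both sets of arrays left out were tests chosen only after the result was seen. Counts below are named by their comparison, with 5066, 449, 168, 6814 and 1498 as first fitted for 7, 14 and 28 days, dissected against saline and dissected against non-dissected, 5092 for the mean of 3 times, 39 at all 3 times, 114 over time in saline, and 278, 193, 497 and 0 for differing effects among times, 14 against 7, 28 against 7 and 28 against 14 days. Except where construction is named, the cause of a move was not tested. All planned settings were run. Of 8675 values of named genes under other settings 7690 were the same, 905 weaker, 70 stronger and 10 reversed, and of 4444 values of lists 4008, 266, 142 and 28.

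The count over time in saline depended most on the setting. It was 0 with limma under several settings, against 114 as first fitted (2372 at an unadjusted p under 0.05). These included the scanner's processed signals, the aorta channel alone, the authors' values, no background correction, the repaired fit, median centring, no filter, the groups compared alone, slide as a block, neighbouring covariates and the arrays of poor fit left out, and it was 0 within scan day 1. It was 1 with both channels filtered, 2 within scan day 2, 8 without the 2 arrays in doubt, 198 with scan day as a block, 344 with array weights and 2488 with scale normalization.

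The scanner's processed signals gave 356 at 28 days, 2721 for dissected against non-dissected, 682 for 14 against 7 days and 241 for 28 against 7 days, and the authors' values gave 427, 2814, 877 and 230, with 68 at all 3 times. The aorta channel alone gave 293 at 14 days, 286 at 28 days, 548 for 14 against 7 and 303 for 28 against 7 days, with Eln at -2.66 in dissected against non-dissected. Without background correction 106 differed among times and 144 between 28 and 7 days, and with the repaired fit 122 and 157. Without the filter 14 against 7 days was 102, and with both channels filtered 7 lists were called between dissected and non-dissected. Myh11 in dissected against saline was at 0.92 and 0.94 with the scanner's and the authors' values, and endothelium at 28 days at -0.18 and -0.15. Aquantile left the ratios as they were by construction.

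Median centring gave 1563, 121 and 67 at 7, 14 and 28 days, 2213 for the mean, 14 at all 3 times, 24 among times, 30 and 12 for 14 and 28 against 7 days, and interferon response at 14 days at -0.023. Scale normalization gave 878, 6 and 4097, 3342 for the mean, 2078 and 77 for the dissected comparisons, 5 at all 3 times, 14 among times, and 9 and 19. By construction it stretched the arrays whose ratios the poor background fit had compressed. At 28 days it put C4b at -3.08, Ccl8 at -0.22, Ctsb at -0.49, Hba-a1 at -5.04, Postn at -5.78, complement at -1.63, endothelium at -2.12, the renin-angiotensin system at -0.69 and white adipocyte at -5.41.

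Array weights gave 7901 at 7 days, 993 at 14, 260 at 28, 5211 for dissected against non-dissected, 75 at all 3 times, 2512 among times, 2599 and 1944 against 7 days, and white adipocyte at 28 days at -0.15. The groups compared alone gave 113 at 14 days, 0 with limma at 28 days and 2320 for dissected against non-dissected. A fold of at least 1.5 left 1401 of the mean, and an unadjusted p of 0.01 gave 198 at all 3 times. With an estimated correlation camera called 0 lists at 7 days, 0 at 14, 1 at 28 and 0 in both dissected comparisons, and fry called 4 at 14 days, 6 at 28 and 0 for dissected against non-dissected.

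Slide as a block gave 3232 at 7 days, 653 at 28, 4338 and 295 for the dissected comparisons, 76 at all 3 times, 79 among times, and 28 and 174 against 7 days. Scan day as a block gave 873 for dissected against non-dissected and 82 for 14 against 7 days. Within scan day 1 the counts were 2747, 19 and 11 at the 3 times, 2972 for the mean, 6 at all 3 times, 2 among times, 1, 13 and 1 for 14 against 7, 28 against 7 and 28 against 14 days. There B cells and T cells at 28 days were at -0.43 and -0.30, and contractile smooth muscle at 0.18 and 0.76 at 14 and 28 days. Within scan day 2 they were 205, 1 and 1469, 1329 for the mean, 8 for dissected against non-dissected, 1 at all 3 times, 13 among times, 0 with limma and 134 against 7 days. There brown adipocyte and hepatocyte at 7 days were at 0.13 and 0.06, and at 28 days collagens at -0.15, collagen processing at -0.16, elastic fibres at -0.14, matricellular proteins at -0.45 and complement at -0.003.

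Replicate numbers did not pair the arrays, since 38 of 91 same-number pairs correlated over 0.1, with a median of 0.05, and 1 of 21 pairs of groups, saline and dissected at 7 days, had every pair over 0.1 (3 pairs, 0.13 to 0.498). With replicate number as a block the counts were 0 over time in saline, 153 among times, 294 for 14 against 7 and 231 for 28 against 7 days. Dissected against saline had 3643 genes higher and 3478 lower with the block. There elastic fibre components at 0.80 and platelets at 0.49 lost their calls (adjusted p = 0.112 for both), and contractile smooth muscle at -1.19, hepatocyte at -2.27 and circadian clock at -0.58 were called.

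Neighbouring tissue covariates left 756, 209 and 96 at 7, 14 and 28 days, 23 at all 3 times, 4 among times, 0 with limma and 28 against 7 days, and 7 lists between dissected and non-dissected. At 7 days white adipocyte was at 0.25, brown adipocyte at 0.10, neurons at 0.081, hepatocyte at 0.062 and Th at 0.08. At 14 days contractile smooth muscle was at 0.11, kidney tubule at 0.048, Slc34a1 at 0.052 and cholesterol synthesis at -0.007, and at 28 days B cells at -0.094. By construction lists used as covariates end near 0. Without the 2 arrays in doubt, Ang II 14-day replicate 4, with 84.8 percent of spots above background, and saline 28-day replicate 5, the counts were 81 at 14 days, 20 at all 3 times and 260 for 28 against 7 days, with contractile smooth muscle at 28 days at 0.044. Without the arrays of poor fit, with 2 saline left at 28 days, they were 1 there, 0 at all 3 times, 112 among times and 51 for 28 against 7 days.

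With one array left out the counts ran from 3201 to 5524 at 7 days, 73 to 721 at 14, 68 to 416 at 28, 4426 to 5373 for the mean, 4992 to 6881 and 704 to 1438 for the dissected comparisons, 87 to 561 among times, 28 to 1018 and 159 to 1097 against 7 days, 0 to 1 for 28 against 14 days, 0 to 610 in saline and 21 to 68 at all 3 times. Lists called ran from 21 to 23, 13 to 20, 16 to 23, 9 to 14 and 9 to 13, and 20 of 23, 12 of 18, 10 of 20, 9 of 12 and 9 of 11 called lists kept their call throughout. At 7 days hepatocyte and interferon response each lost it without 5 of 10 arrays in turn. Platelets at 14 days ran from -0.294 without saline replicate 1 to 0.02 without replicate 3, and contractile smooth muscle at 28 days from -0.828 without saline replicate 2 to 0.044 without replicate 5. At all 3 times the count was 21 and 25 without Ang II 14-day replicates 4 and 3, 25 and 68 without saline 14-day replicates 1 and 6, 25 without saline 28-day replicate 4 and 62 without Ang II 28-day replicate 2.

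In saline the count was 0 without 7-day replicate 2, 14-day replicates 1, 2, 3, 4 or 6, or 28-day replicates 1, 2 or 4. It was 3 and 11 without replicate 5 of 14 and 28 days, 62, 460 and 61 without 7-day replicates 1, 5 and 6, and 610 without 28-day replicate 3. Among times it was 109 and 87 without Ang II 7-day replicates 1 and 2, 146 and 157 without saline 7-day replicates 4 and 6, and 561 and 183 without saline 28-day replicates 3 and 4.

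For 14 against 7 days it was 57 and 28 without Ang II 7-day replicates 1 and 2, 59, 110 and 78 without Ang II 14-day replicates 1, 3 and 5, 538, 85, 722, 64, 107 and 85 without saline 7-day replicates 1 to 6, and 81, 88, 75 and 1018 without saline 14-day replicates 2 to 5. For 28 against 7 days it was 195, 159 and 872 without Ang II 7-day replicates 1 to 3, 315, 884, 965 and 228 without Ang II 28-day replicates 2, 3, 5 and 6, 257, 769 and 237 without saline 7-day replicates 4 to 6, and 774, 1097, 226 and 261 without saline 28-day replicates 2 to 5. Without Ang II 28-day replicate 1 the count for 28 against 14 days was 1.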

Other observations

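Erythroid genes had medians of 0.19, 0.03 and 0.12 at 7, 14 and 28 days and 0.07 in dissected aortas, mast cells 0.14, 0.15, 0.46 and -0.20, and immediate early genes 0.16, -0.22, -0.05 and 0.15, and none of these passed. Bone and cartilage, called at 7 days, stood at 0.14 and -0.10 later.

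Saline scores varied most for hepatocyte, with a standard deviation of 1.27 within groups, neurons with 1.06, contractile smooth muscle with 0.871 and brown adipocyte with 0.832, against 0.257 for cell cycle and 0.368 for macrophages. For the neuron genes, whose catecholamine and general members correlated at 0.983 in saline aortas, neighbouring tissue on single aortas is a candidate explanation. It was not tested for smooth muscle.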
